A study of Mus musculus with 24 samples.

How the data were processed

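Whole hypothalamus was taken from male BPH/2J and BPN/3J mice at 6 and 26 weeks of age, with 6 mice in each of 4 groups and no pooling, and total RNA was hybridised to Affymetrix Mouse Gene 1.0 ST arrays. The deposited table holds log2 values for 34760 probe sets on 24 arrays, made with RMA, per the submitters' processing notes, which also name limma. RMA subtracts background, makes the distributions of the arrays equal and summarises the probes of a probe set, so a shift shared by all genes of an array is removed before deposition and differences are relative to the other genes of the array. The versions of these tools, the array annotation and any genome build are not given in the sources used here. The values ran from 1.54 to 14.3 with 0 missing. Arrays have no read depth, and their number limits the precision. Signal over background was not given per probe set, so dim genes may be measured with less contrast. Where a named gene had an array of its dimmer group at or below that array's median of all unnamed probe sets, a rule set after the data were seen, values below the median were raised to it to give the difference as a lower bound; unnamed probe sets are not known to be free of transcripts.

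Groups and replicate numbers came from the sample titles. The design text once gives the normotensive strain another substrain suffix, and the name of the sample labels was kept. Probe sets were named through the platform annotation table, in which 21640 had 1 gene symbol, 1321 had several and 11799 of the table's probe sets were unnamed, 6573 of them numbered below the first named one. Entrez identifiers matched 21553 of the single-symbol probe sets to a RefSeq gene table of assembly GRCm38.p6, which was used for names and for which genes are neighbours, and 0 symbols changed. A gene was represented by its probe set with the highest mean over all arrays, which gave 19937 genes; 954 genes had more than 1 probe set. Probe sets with several symbols or none were left out of the gene tests. No array was left out.

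Differences were fitted with limma 3.58.1 in R 4.3.3. The model had a mean per group and all 24 arrays, which share one spread with 20 residual degrees of freedom, and moderated statistics. It gave 5 contrasts: strain at each age, the strain by age interaction, and age in each strain. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05. Standard errors are those of the moderated fit. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists and contrasts, again with an estimated correlation, and with fry. Of 26 lists 25 had at least 5 measured genes; the red blood cell list had 4 measured and was given counts only, with 0 called in each contrast. The lists held 674 entries, of which 615 were analysed. A gene that belonged to several lists was counted in each of them. List means per array were compared with exact permutation tests of 6 against 6 arrays, two-sided, adjusted over 104 tests.

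Except for the lower-bound rule for dim genes, the choices so far were made before the data were examined, as was the rule for named genes. It takes, for each strain contrast, the 8 higher and 8 lower genes with the largest difference among called genes without overlap between the strains. For the interaction it takes up to 5 called genes in each direction, and for each age contrast 6 in each direction without overlap. It adds up to 4 called members of each list, smallest p first, and a fixed set of 15 genes of hypothalamic and blood pressure interest, 14 of them analysed here and given at both ages whether called or not.

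The code was tested on simulated data with 200 of 19937 genes changed, in 20 runs per contrast. With the same SD in all groups, the share of false calls was 5.19% for strain at 6 weeks and 5.23% at 26 weeks, 5.52% for the interaction, and 5.09% and 5.52% for age in BPH/2J and BPN/3J. Changes of 1 log2 unit were recovered in 99.0%, 99.0%, 95.5%, 99.2% and 99.1% of cases, and changes of 0.5 in 81.5%, 80.5%, 49.8%, 81.1% and 80.2%, in the same order. With each group's own SDs, which breaks the assumption of a shared spread, the false share was 5.59%, 31.2%, 9.06%, 14.9% and 12.4%. With only the groups compared in the fit it was 6.90% for strain at 6 weeks, 6.11% at 26 weeks, 6.61% for age in BPH/2J and 8.21% in BPN/3J. SDs estimated from 6 arrays also differ between groups by chance, which adds to these shares. A false share also depends on how many genes truly change, so these shares are not estimates for the real calls. The fixed fit on all arrays was kept. The narrower fit called 2322 genes for strain at 6 weeks, 1440 of them among the 1479, and 2502 (2389 shared) and 2375 (2036 shared) for age in BPH/2J and BPN/3J.

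No pair of arrays within a group was a duplicate: mean absolute differences were at least 0.12. Same-numbered arrays were checked for pairing through the correlation of their deviations from group means. The 26-week strains had correlations of 0.13 to 0.44 in 6 of 6 pairs, above the limit of 0.1 set in advance, and the other pairs of groups did not all pass it. The labels do not say what a number stands for. Same-numbered 26-week arrays of the strains also share an array set, as given with the age comparisons, so these correlations cannot tell pairing from the sets. Alternatives covered repeated quantile normalisation, median centring, leaving out the dimmest genes, other summaries of probe sets, a replicate block, fits on the groups compared, a variance trend with a robust prior, array weights, other thresholds and leaving out each array. Chosen after the data were seen were the array set as a term, each array set alone and the thalamus list mean as a covariate.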

Results

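Gene expression in the whole hypothalamus was measured on 24 arrays, each from a separate male mouse, in 4 groups of n = 6. The mice were BPH/2J, an inbred strain with high blood pressure, and BPN/3J, the strain with normal blood pressure used beside it. Each strain was sampled at 6 and at 26 weeks of age, at the peak of the daily blood pressure cycle. Values were RMA values on the log2 scale, with array medians between 5.89 and 6.09, and the mean correlation of an array with the others of its group was 0.986 to 0.997 over genes. The number of arrays limits the precision, and the median standard error of a strain or age difference was 0.09 log2 units over 19937 genes.

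The first comparison asked which genes differ between the hypertensive and the normotensive strain in young mice. At 6 weeks the predicted gene AI506816 was higher in BPH/2J by at least 5.32 log2 units (measured 5.77 ± 0.26, SE, n = 6 per group), and Gdpd3, a phospholipase D-type enzyme that makes lysophospholipids, by at least 3.00 (measured 3.06 ± 0.14). Both are lower bounds, since the BPN/3J values, 3.97 to 4.83 and 4.54 to 4.98, were not clear of the level of the 11799 unnamed probe sets (array medians 4.71 to 4.76). Over the 6573 of them numbered below the first named one, the array medians were 4.47 to 4.52, and Gdpd3 lay above these on every 6-week BPN/3J array. Cthrc1, a secreted collagen triple helix repeat protein, was higher by 2.31 ± 0.10, Gm1976 by 1.80 ± 0.10 and Pla2g4e, a cytosolic phospholipase A2 family member, by 1.67 ± 0.08. The neuropeptide gene Gal was higher by 1.56 ± 0.18, Gda, a guanine deaminase, by 1.55 ± 0.32 and the chemokine gene Ccl19 by 1.53 ± 0.35. Lower in BPH/2J were 1810037I17Rik (-1.95 ± 0.19, near that level in BPH/2J, and lower by at least 1.89), Tmem267 (-1.88 ± 0.08), Eif4a3 (-1.86 ± 0.20), 4833420G17Rik (-1.82 ± 0.12), Gm14403 (-1.71 ± 0.22), Medag (-1.68 ± 0.16), the non-coding RNA Gas5 (-1.66 ± 0.11) and Endou (-1.56 ± 0.13). All of these genes passed limma's test at an adjusted p below 0.05, and for each the 6 arrays of one strain lay wholly above the 6 of the other. The rule for naming them required both. In all, 1479 of 19937 genes were called, 597 higher and 882 lower in BPH/2J. Of these 356 differed by at least 1.5-fold and 737 had no overlap between the strains.

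**Figure D1:**
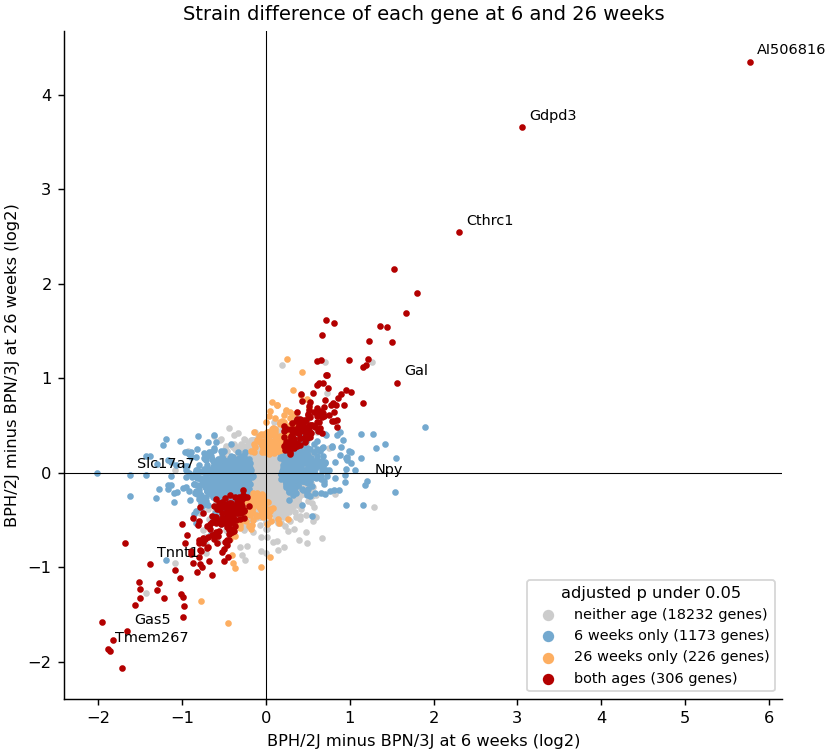
Log2 difference between BPH/2J and BPN/3J at 6 weeks (horizontal axis) and at 26 weeks (vertical axis), with a point for each of 19937 genes and colours for the ages at which a gene passed the test. The 306 genes called at both ages lie in the upper right and lower left, while Slc17a7 and Npy lie near 0 on the 26-week axis.

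Among the neuropeptides of the hypothalamus, 10 of 34 measured genes were higher and 2 lower in BPH/2J at 6 weeks, and 14 and 2 when adjusted over the list alone. Npy, a peptide that drives feeding, was higher by 1.21 ± 0.23, Ghrh, the growth hormone releasing hormone, by 0.75 ± 0.15 and Pmch, the precursor of melanin-concentrating hormone, by 0.70 ± 0.15. Pomc, the precursor of melanocortins, was higher by 1.54 ± 0.36 and Hcrt, the orexin precursor, by 1.00 ± 0.29. Hcrt at 6 weeks did not pass without BPH/2J replicate 1, 3, 4 or 6 or BPN/3J replicate 1, 2, 4 or 5 (highest adjusted p 0.103, lowest value 0.88). Avp (0.70 ± 0.42), Oxt (0.19 ± 0.50) and Crh (-0.12 ± 0.16) did not pass. The camera test called the list higher (adjusted p = 5.29e-05, and adjusted p = 0.644 with an estimated correlation). The mean of the list over arrays was higher by 0.37 ± 0.09, which gave p = 0.00866 in a two-sided exact permutation test and 0.0600 after adjustment over 104 such tests. Of 44 neuropeptide receptors 7 were higher and 2 lower, and 10 and 2 when adjusted over the list alone. Calcr, the calcitonin receptor, was higher by 1.02 ± 0.22 and the melanocortin receptor gene Mc3r by 0.70 ± 0.15, while Vipr2, a receptor of vasoactive intestinal peptide, was lower by -0.80 ± 0.15; Vipr2 is also a member of the thalamus list. This list too was called higher by camera (adjusted p = 0.000322, and adjusted p = 0.644 with an estimated correlation). The thalamus marker mean, given next, differed between the same groups.

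Markers of the thalamus, the region above the hypothalamus, were lower in 6-week BPH/2J in 13 of 16 measured members with none higher, and 15 and 0 when adjusted over the list alone. Tnnt1 was lower by -1.39 ± 0.14, Plekhg1 by -1.62 ± 0.26, Rora by -1.13 ± 0.17 and the transcription factor gene Lef1 by -0.95 ± 0.16. The list mean was 8.62 ± 0.57 (SD, n = 6) in BPH/2J against 9.59 ± 0.12 in BPN/3J. BPH/2J replicate 2 stood at 9.50, inside the BPN/3J range of 9.48 to 9.82, and the other 5 lay between 7.93 and 8.91. The exact permutation p of the difference of -0.96 ± 0.24 was 0.00433, or 0.0600 after adjustment. Camera called the list lower (adjusted p = 8.19e-19, and adjusted p = 0.565 with an estimated correlation). With this list mean as a covariate, an alternative chosen after the data were seen, 155 genes were called at 6 weeks, 143 of them from the 1479.

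Oligodendrocyte and myelin markers were lower in BPH/2J at 6 weeks for 9 of 22 measured genes with none higher, and for 16 and 0 when adjusted over the list alone. Trf, the transferrin gene, was lower by -0.77 ± 0.13, Fa2h, an enzyme of myelin lipid synthesis, by -0.74 ± 0.15 and Opalin by -0.75 ± 0.18. Camera called the list lower (adjusted p = 2.07e-10, and adjusted p = 0.644 with an estimated correlation). Voltage-gated ion channels moved both ways, with 12 lower and 5 higher of 39, and 18 and 6 when adjusted over the list alone. Scn4b, a sodium channel subunit, was lower by -1.43 ± 0.25, whereas Scn9a was higher by 1.01 ± 0.14 and Kcnn2 by 0.49 ± 0.07. The channel list was called lower by camera (adjusted p = 0.000379, and adjusted p = 0.688 with an estimated correlation). Of 36 oxidative phosphorylation genes 3 were lower, also when adjusted over the list alone, and the list was called lower with a mean of -0.07 (adjusted p = 0.00984, and adjusted p = 0.731 with an estimated correlation). Atp5g1 was among them at -0.27 ± 0.07 and stood at 0.15 when all its probe sets were averaged; it did not pass without BPH/2J replicate 5 (-0.24, adjusted p = 0.0531). The thalamus marker mean was lower by 0.96 in the same arrays as each of these groups.

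Of the 6 lists that camera called at 6 weeks, fry called all but voltage-gated channels (adjusted p = 0.0996) and oxidative phosphorylation (adjusted p = 0.136). Lists that camera did not call at that age also held called members. In the GABA system, which fry did call (adjusted p = 0.0302), Gabre and Gabrq, subunits of the GABA-A receptor, were higher by 1.14 ± 0.17 and 0.96 ± 0.15, Gabra2 was higher by 0.42 ± 0.10, and Gabrd was lower by -1.23 ± 0.25; of 22 genes 7 were higher and 4 lower, and 8 and 5 when adjusted over the list alone. In the glutamate system Slc17a7, a vesicular glutamate transporter also listed as a cortical marker, was lower by -1.62 ± 0.30, with 1 of 28 higher and 4 lower, and 4 and 5 when adjusted over the list alone. Nos1, the neuronal nitric oxide synthase, was higher by 0.44 ± 0.10 and Prkg1, a cGMP-dependent kinase, by 0.72 ± 0.11; this list of 20 had 4 genes each way under both adjustments. In the renin-angiotensin-aldosterone list none of 17 genes passed limma's test, and 0 and 2 did when adjusted over the list alone, with Agt at 0.17 ± 0.07 and Agtr1a at 0.11 ± 0.13. Th (-0.72 ± 0.41), Fos (-0.09 ± 0.21) and Per2 (0.23 ± 0.09) did not pass. B2m, the light chain of MHC class I, was lower by -0.77 ± 0.10 and the complement gene C1qc, a microglia marker, by -0.81 ± 0.09. With the thalamus list mean as a covariate Gabrd stood at 0.11 and Slc17a7 at -0.27, and neither passed.

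**Figure D2:**
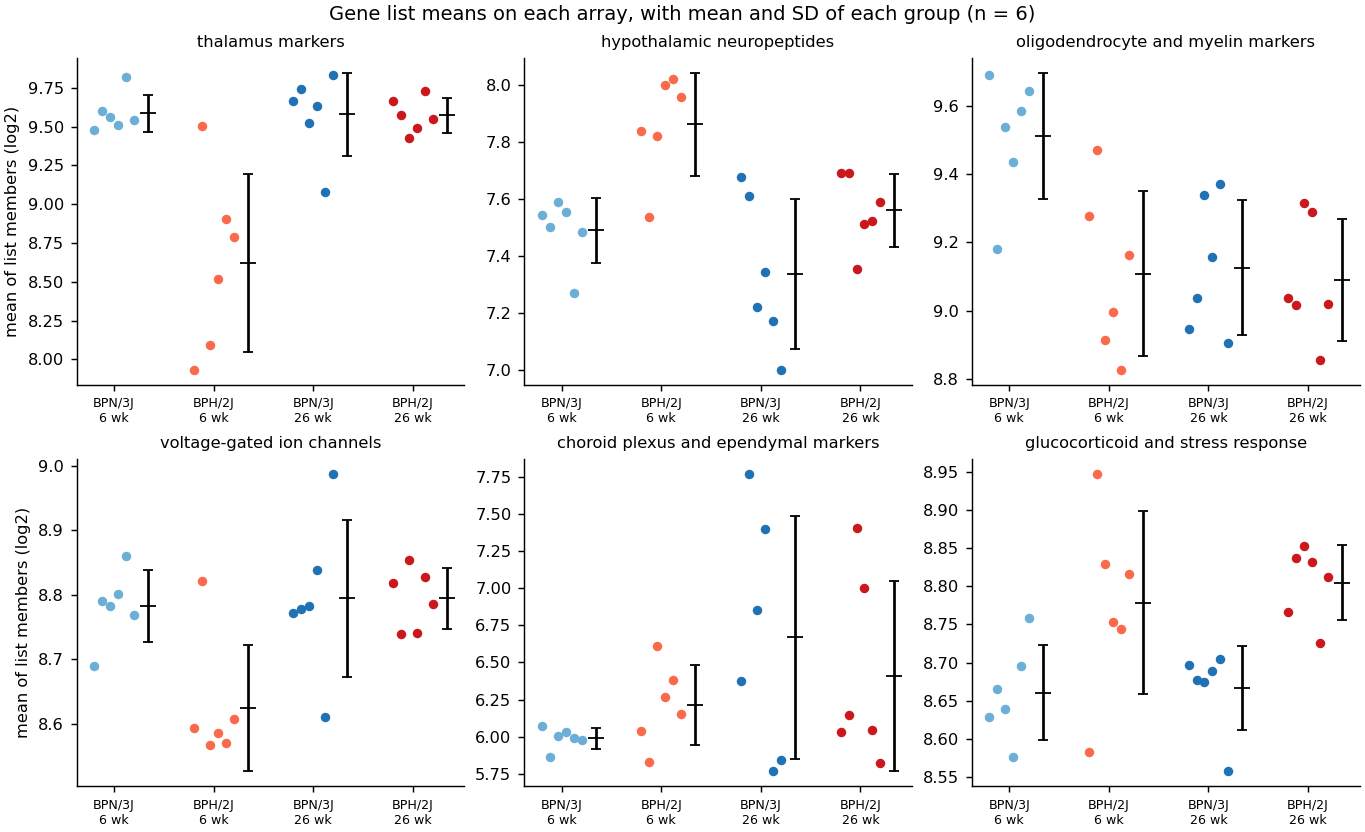
Mean RMA value (log2) of the members of 6 gene lists on each array, with the group mean and SD (n = 6 arrays). Thalamus markers range from 7.93 to 9.50 in 6-week BPH/2J and from 9.48 to 9.82 in 6-week BPN/3J.

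The second comparison asked the same of adult mice. At 26 weeks AI506816 was higher in BPH/2J by at least 3.57 log2 units (measured 4.35 ± 0.26, SE, n = 6 per group) and Gdpd3 by at least 3.41 (measured 3.66 ± 0.14), again with BPN/3J at the level of the 11799 unnamed probe sets. Cthrc1 was higher by 2.55 ± 0.10, Ccl19 by 2.15 ± 0.35, Gm1976 by 1.90 ± 0.10 and Pla2g4e by 1.69 ± 0.08. Slc25a31, an ADP/ATP carrier best known from testis, was higher by 1.62 ± 0.14 and Sycp3, a protein of meiotic chromosomes, by 1.59 ± 0.20. Gm14403 (-2.07 ± 0.22), Eif4a3 (-1.89 ± 0.20), Tmem267 (-1.87 ± 0.08), 4833420G17Rik (-1.78 ± 0.12), Gas5 (-1.67 ± 0.11), 1810037I17Rik (-1.59 ± 0.19), Nat8f2 (-1.52 ± 0.13) and Phkg1, a phosphorylase kinase subunit (-1.41 ± 0.12), were lower. Slc25a31 (at least 0.66), Sycp3 (at least 1.51) and Nat8f2 (lower by at least 1.07) were at that level in the dimmer strain, and their bounds are given here. The test of limma called 532 genes, 264 higher and 268 lower, of which 153 differed by at least 1.5-fold. With a term for the sets of 26-week arrays given with the age comparisons, chosen after the data were seen, 881 were called. Gene SDs were larger at 26 weeks (median 0.16 in BPH/2J and 0.18 in BPN/3J) than at 6 weeks (0.14 and 0.10). The shared spread of the fit was tried on simulated data with 200 changed genes and each group's own SDs. It made 31.2% of the calls of this comparison false, against 5.59% at 6 weeks. That share depends on how many genes truly change, so it is not an estimate for the 532. The simulated arrays also held no array sets. With only the 26-week arrays in the fit 248 genes were called, 244 of them among the 532.

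Of the 34 neuropeptide genes 2 were higher in BPH/2J at 26 weeks, also when adjusted over the list alone: Gal by 0.96 ± 0.18 and Hcrt by 1.19 ± 0.29. Hcrt at 26 weeks did not pass without BPN/3J replicate 6 (0.93, adjusted p = 0.0543) or BPH/2J replicate 5 (1.04, 0.0650) or 6 (0.99, 0.0649). Avp was at 1.17 ± 0.42, Oxt at 1.14 ± 0.50 and Pmch at 0.41 ± 0.15, and none of them passed. Npy (-0.09 ± 0.23), Pomc (-0.20 ± 0.36), Nos1 (-0.09 ± 0.10) and Gabra2 (0.12 ± 0.10) did not pass either. The list was called higher by camera (adjusted p = 0.0219, and adjusted p = 0.731 with an estimated correlation). Of 22 glucocorticoid and stress response genes 2 were higher, and 7 when adjusted over the list alone. Fkbp5, a glucocorticoid-induced chaperone partner, was higher by 0.37 ± 0.09 and Plin4, a lipid droplet protein, by 0.51 ± 0.12, and camera called the list (adjusted p = 0.0320, and adjusted p = 0.731 with an estimated correlation). Oxidative phosphorylation had 2 of 36 genes higher, also when adjusted over the list alone, which were the succinate dehydrogenase subunits Sdhc (0.39 ± 0.09) and Sdhb (0.29 ± 0.07). It was called higher (adjusted p = 0.0146, and adjusted p = 0.731 with an estimated correlation). Without BPH/2J replicate 2 at 26 weeks, 0 lists were called by camera. The neuropeptide call at 26 weeks was also lost without BPH/2J replicate 1 or BPN/3J replicate 3, 5 or 6 (highest adjusted p 0.120), the stress response call without BPH/2J replicate 3 or 4 or BPN/3J replicate 5 or 6 (0.149) and the oxidative phosphorylation call without BPH/2J replicate 4 or BPN/3J replicate 1 (0.0722). Fkbp5 did not pass without BPH/2J replicate 2 or BPN/3J replicate 3 (0.0532), Plin4 without BPN/3J replicate 2 (0.0545), or Sdhc without BPH/2J replicate 1, 2 or 4 or BPN/3J replicate 6 (0.0622).

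Other called genes at 26 weeks were the clock output gene Dbp (0.41 ± 0.07), Ciart (0.58 ± 0.13) and Cry2 (0.22 ± 0.06); of 23 clock genes 3 were higher and none lower, and 4 and 1 when adjusted over the list alone. Cry2 did not pass without BPH/2J replicate 1, 2, 5 or 6 or BPN/3J replicate 2, 3 or 4 (highest adjusted p 0.107). B2m was lower by -0.83 ± 0.10 and C1qc by -0.55 ± 0.09, and Slco1a4, a transporter of brain vessels, was higher by 0.66 ± 0.11. Agt (0.18 ± 0.07), Agtr1a (0.08 ± 0.13), Crh (0.16 ± 0.16), Th (-0.68 ± 0.41), Fos (-0.43 ± 0.21) and Per2 (0.15 ± 0.09) did not pass. The thalamus marker mean differed by -0.01 ± 0.12 between the strains at 26 weeks (exact permutation p = 0.970), and Tnnt1 was the called member at -0.97 ± 0.14.

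The strains were then compared across ages. The 306 genes called at both ages all had the same direction, 144 higher and 162 lower in BPH/2J, where independent lists of these sizes would share 7.91 and 11.9. Of them 29 differed at least 2-fold at both ages, and the median ratio of the 26-week to the 6-week difference was 1.02. With only the groups compared in each fit, 197 of the 306 were called at both ages. Over all 19937 genes, which are not independent replicates, the differences at the 2 ages correlated at r = 0.431 (rho = 0.205). Of the genes called at 6 weeks 75.4% had the same sign at 26 weeks.

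**Figure D3:**
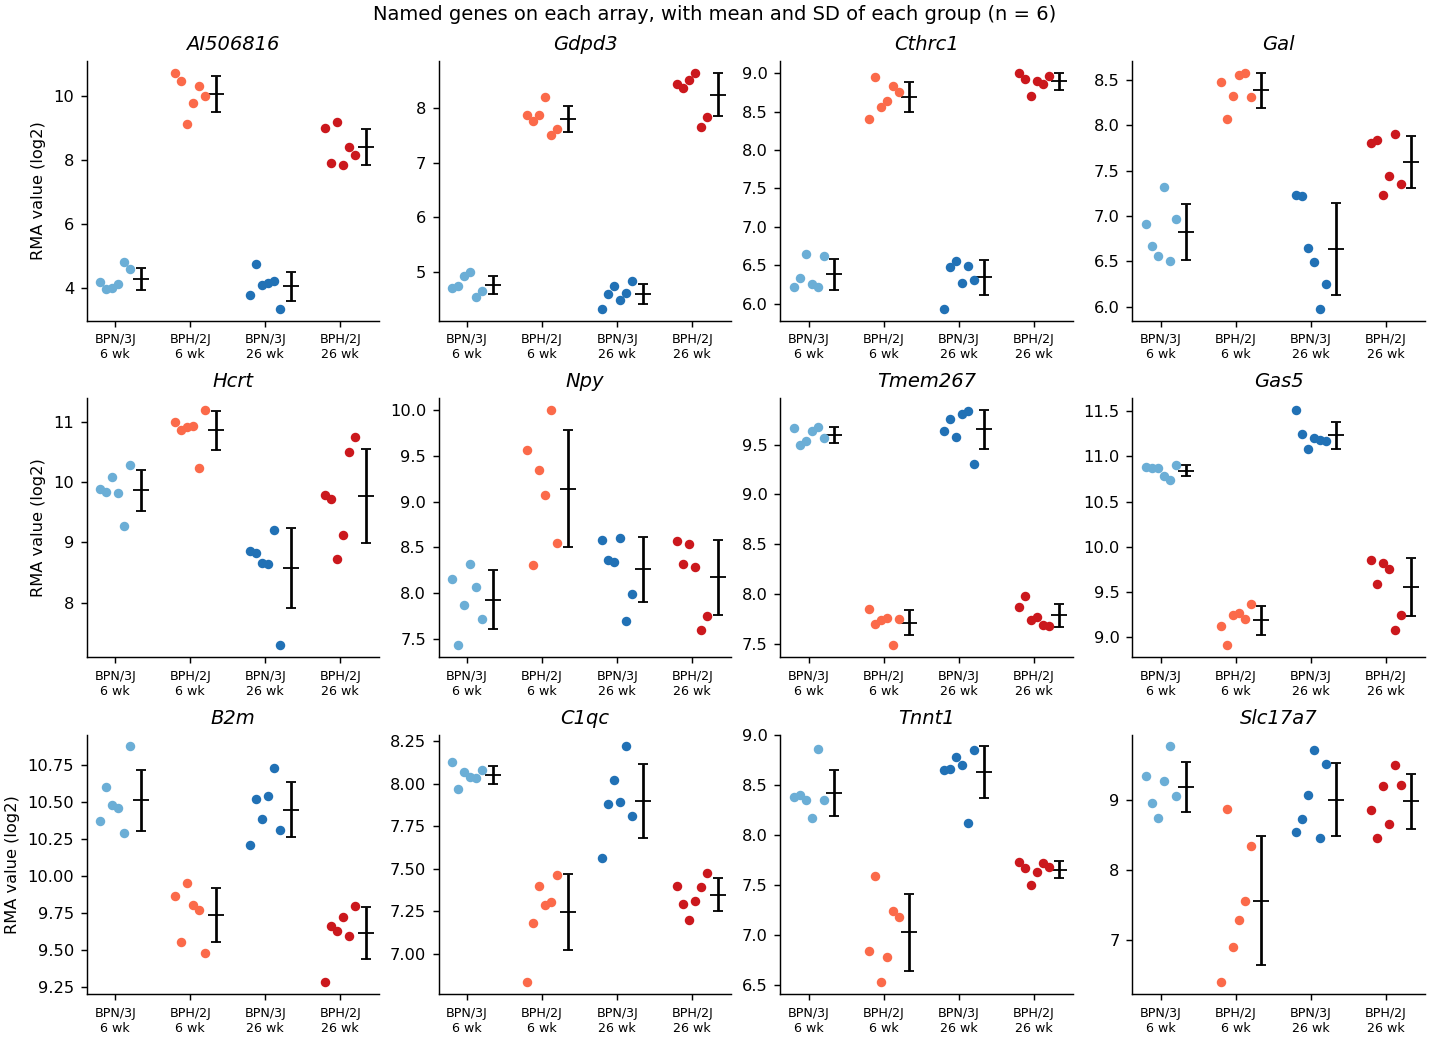
RMA value (log2) of 12 named genes on each array, with the group mean and SD (n = 6 arrays) and a separate vertical scale per gene. Gdpd3, Cthrc1, Tmem267, Gas5, B2m and C1qc part the strains at both ages, while Slc17a7 and Npy overlap at 26 weeks.

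A direct test asked for which genes the strain difference depended on age. Srpx2, a secreted sushi-repeat protein, had a more positive strain difference at 26 than at 6 weeks by 1.01 ± 0.18 log2 units (SE, n = 6 per group). The difference was more negative at 26 weeks for Slit2, an axon guidance ligand (-0.99 ± 0.18), N4bp2 (-0.88 ± 0.15), Dgkk, a diacylglycerol kinase (-0.78 ± 0.13), Ptpro, a receptor phosphatase (-0.78 ± 0.15), and Coq8b, a kinase of coenzyme Q synthesis (-0.56 ± 0.10). These 6 were all the genes past limma's test, with 2160 at an unadjusted p below 0.05. None of the 306 genes called at both ages was among them. Leaving out 1 array gave 0 such genes in 14 of 24 fits, and each of the 6 lost its call in 14 to 21 of the fits. The count was 496 without 6-week BPH/2J replicate 2, the array with thalamus markers at the BPN/3J level, and 0 with the thalamus list mean as a covariate. It was 251 with a term for the sets of 26-week arrays given with the age comparisons.

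Thalamus markers had the largest interaction of the lists, 0.96 log2 units, with 0 of 16 members past the test over all genes and 15 higher and 0 lower when adjusted over the list alone (camera adjusted p = 4.61e-17, and adjusted p = 0.565 with an estimated correlation). Oligodendrocyte and myelin markers had 0.37 (adjusted p = 0.687 with an estimated correlation), choroid plexus and ependymal markers -0.48 (adjusted p = 0.773 with an estimated correlation) and neuropeptide receptors -0.17 (adjusted p = 0.644 with an estimated correlation). Voltage-gated channels had 0.16 (adjusted p = 0.731 with an estimated correlation), clock genes 0.16 (adjusted p = 0.644 with an estimated correlation) and oxidative phosphorylation 0.14 (adjusted p = 0.644 with an estimated correlation). Without 26-week BPN/3J replicate 2 the choroid plexus interaction was -0.26 and not called (adjusted p = 0.109), and the list mean ran from 5.77 to 7.77 in that group. Without BPN/3J replicate 5 of that age the channel interaction was 0.12 and not called (adjusted p = 0.0694). No member of these lists passed over all genes. Adjusted over the list alone, 5 oligodendrocyte and 5 clock genes were more positive, 17 channel genes were more positive and 5 more negative, and 1 receptor gene was more negative.

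The last comparisons asked what differed between 6 and 26 weeks within each strain. In BPH/2J the transporter gene Abca8a rose with age by 1.40 ± 0.14 log2 units (SE, n = 6 per group) and the cytokine gene Il33 by 1.25 ± 0.14, while Gpr17, a receptor of oligodendrocyte precursors, fell by 1.01 ± 0.09. Mlip (1.43 ± 0.20), Tcf7l2 (1.32 ± 0.21), Kitl (1.26 ± 0.19) and Zic2 (1.15 ± 0.19) were higher at 26 weeks, and Hdc, the histamine-forming enzyme (-1.36 ± 0.33), Baiap3 (-1.31 ± 0.16), Gabrq (-1.05 ± 0.15), Mir382 (-0.97 ± 0.25) and the peptide gene Cartpt (-0.95 ± 0.15) were lower. In BPN/3J Abca8a rose by 1.45 ± 0.14 and Il33 by 0.99 ± 0.14, and Gpr17 was lower by -1.02 ± 0.09. Npas4, an activity-regulated transcription factor (0.87 ± 0.20), the sodium channel gene Scn7a (0.87 ± 0.25), BC002059 (0.82 ± 0.14) and Rps4x (0.77 ± 0.16) were higher, and Hcrt (-1.29 ± 0.29), Carnmt1 (-0.85 ± 0.24), the myelin gene Mal (-0.78 ± 0.12), Cartpt (-0.77 ± 0.15) and Tspan2 (-0.77 ± 0.10) were lower. With the thalamus list mean as a covariate 8 genes were called with age in BPH/2J, and of the 12 BPH/2J genes named here 3 kept their calls, Abca8a, Il33 and Gpr17; Tcf7l2 is itself a member of the list. All 12 named in BPN/3J kept theirs. In BPN/3J Scn7a did not pass without 6-week replicate 3 or 26-week replicate 1, 2 or 4 (lowest value 0.75, highest adjusted p 0.0775), and Carnmt1 without 26-week replicate 1 or 2 (-0.64 without replicate 2, adjusted p = 0.0642). The test of limma called 3362 genes in BPH/2J, 1640 higher and 1722 lower at 26 weeks, and 2445 in BPN/3J, 917 higher and 1528 lower. These counts depend on single arrays: that of BPH/2J was 2138 without 26-week replicate 4, and that of BPN/3J was 1299, 1521 and 1545 without 6-week replicates 1, 3 and 4, 1382, 1151 and 1034 without 26-week replicates 1, 2 and 4, and 4230 without 26-week replicate 5. Both strains shared 994 calls, 990 of them in the same direction, and the age differences correlated across genes at r = 0.559. Of the 990, 356 were higher and 634 lower at 26 weeks, where independent lists of these sizes would share 75.4 and 132. Both 26-week groups hold the same mix of the array sets given next, so agreement between the strains can also come from the sets.

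The 26-week arrays fell into sets that cut across the strains. In both strains replicates 1 to 4 had scores of 13.045 or more on the second component of the 6573 unnamed probe sets numbered below the first named one, and all other arrays had -3.99 or less. Against the 6-week mice, replicates 1 to 4 gave 7843 called genes in BPH/2J and 6702 in BPN/3J, and replicates 5 and 6 gave 388 and 27. Both sets were compared with the same 6-week arrays, so their results are not independent. Genes called from each set in the same direction numbered 214 in BPH/2J and 14 in BPN/3J. Abca8a, Gpr17 and Pex5, singled out after their values were seen, were called from each set in each strain. Of the 12 genes named above in each strain, all were called from replicates 1 to 4, and replicates 5 and 6 gave calls for 9 in BPH/2J and 2 in BPN/3J. In BPN/3J Npas4 was at 1.18 and 0.24 from the sets in turn, Scn7a at 1.13 and 0.35, Rps4x at 1.02 and 0.26 and BC002059 at 0.98 and 0.52. Other genes not called from replicates 5 and 6 had changes of similar or larger size there. In BPH/2J these were Tcf7l2 (1.36 and 1.25), Kitl (1.30 and 1.17) and Mir382 (-0.95 and -1.01). Hcrt in BPN/3J was at -1.12 and -1.62, but the second value rests on 26-week replicate 6 (7.29), which stood apart from its group. Replicate 5 was at 9.20, above replicates 1 to 4 (8.65 to 8.86). Replicates 5 and 6 are 2 arrays, so that comparison has less power.

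**Figure D4:**
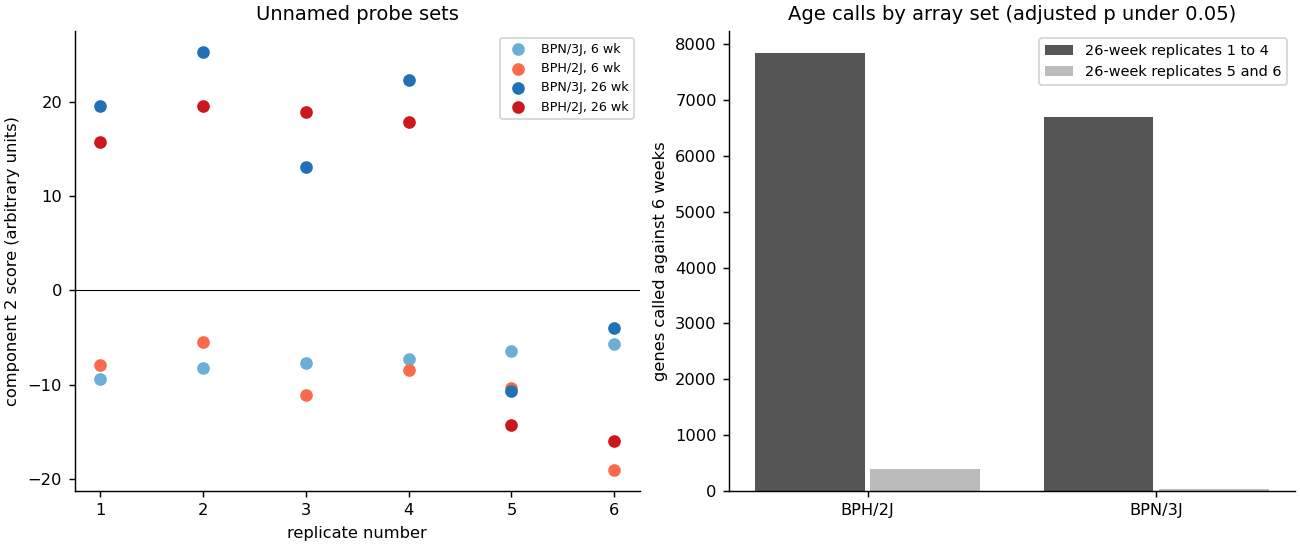
Left, score of each array on the second component of 6573 unnamed probe sets against its replicate number. Right, number of genes called between 6 and 26 weeks when the 26-week group held replicates 1 to 4 or replicates 5 and 6; replicates 1 to 4 at 26 weeks have scores of 13.045 or more.

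Camera called 9 lists with age in BPH/2J. Fry called all of them but microglia markers (adjusted p = 0.0775), and it also called pituitary markers (adjusted p = 0.0373), which camera did not. Thalamus markers were higher at 26 weeks in 13 of 16 genes, and 15 when adjusted over the list alone, with Plekhg1 at 1.69 ± 0.26 (adjusted p = 0.632 with an estimated correlation). Voltage-gated channels had 15 of 39 genes higher and 5 lower, and 22 and 5 when adjusted over the list alone, led by Cacnb4 at 0.54 ± 0.07 (adjusted p = 0.687 with an estimated correlation). Of 36 oxidative phosphorylation genes 12 were higher and 1 lower, and 14 and 2 when adjusted over the list alone, with Ndufb8 at 0.43 ± 0.08 (adjusted p = 0.687 with an estimated correlation). Of 23 clock genes 8 were higher and 1 lower, and 10 and 2 when adjusted over the list alone, with Hlf at 0.60 ± 0.09 (adjusted p = 0.632 with an estimated correlation). Of 17 microglia markers 4 were higher, and 6 when adjusted over the list alone, with Gpr34 at 0.47 ± 0.12 (adjusted p = 0.697 with an estimated correlation). Neuropeptides had 8 of 34 genes lower and 1 higher, and 9 and 1 when adjusted over the list alone, with Ghrh at -0.68 ± 0.15 and Gal at -0.79 ± 0.18 (adjusted p = 0.697 with an estimated correlation). Their receptors had 10 of 44 lower and 2 higher, and 15 and 2 when adjusted over the list alone, with Ghsr, the ghrelin receptor, at -0.46 ± 0.10 (adjusted p = 0.687 with an estimated correlation). Of 27 extracellular matrix genes 11 were lower, and 13 lower and 1 higher when adjusted over the list alone, with Sparc at -0.55 ± 0.09 (adjusted p = 0.687 with an estimated correlation). Astrocyte and tanycyte markers had 8 of 20 lower, and 9 when adjusted over the list alone, with Rax at -0.55 ± 0.12 (adjusted p = 0.687 with an estimated correlation). This call was lost without BPH/2J 6-week replicate 1 or 5 or 26-week replicate 1, 5 or 6 (highest adjusted p 0.112). From replicates 5 and 6 alone Plekhg1, Ndufb8 (0.29), Gpr34 (0.22), Ghrh (-0.69), Ghsr (-0.34) and Rax did not pass in BPH/2J. With 2 arrays a lost call does not by itself show a smaller change. The thalamus marker mean was higher by 0.95 over the same arrays as each of these lists.

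In BPN/3J camera called 2 lists with age. Of these fry called oligodendrocyte and myelin markers (adjusted p = 0.0246) and not choroid plexus and ependymal markers (adjusted p = 0.175). Fry also called growth and neurogenesis genes (adjusted p = 0.0377) and astrocyte and tanycyte markers (adjusted p = 0.0348). Oligodendrocyte and myelin markers were lower at 26 weeks in 10 of 22 genes, and 13 when adjusted over the list alone, with Tspan2 at -0.77 ± 0.10, Cldn11, the tight junction protein of myelin, at -1.08 ± 0.17 and Olig1 at -0.45 ± 0.07 (adjusted p = 0.688 with an estimated correlation). Choroid plexus and ependymal markers were higher in 3 of 19 genes, and 4 when adjusted over the list alone, with Clic6 at 1.08 ± 0.33 (adjusted p = 0.731 with an estimated correlation). The others were Cldn2 (measured 0.86) and F5 (measured 0.80). Both were at the level of the unnamed probe sets on 6 of 6 6-week BPN/3J arrays, and their lower bounds were -0.15 and 0.39. They lost their calls in 13 and 16 of 24 fits without 1 array. Clic6 did not pass without BPN/3J 6-week replicate 1, 2, 3, 5 or 6 or 26-week replicate 1, 2 or 4 (highest adjusted p 0.102). With replicates 5 and 6 as the 26-week group the choroid plexus value was -0.18 and Clic6 was at 0.06 (adjusted p = 0.930), against 1.59 from replicates 1 to 4. Tspan2 was then at -0.63, Cldn11 at -0.73 and Olig1 at -0.38, and none of them passed (adjusted p = 0.0887, 0.139 and 0.130). The thalamus marker mean differed by -0.01 ± 0.12 with age in BPN/3J (exact permutation p = 0.974).

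In the exact permutation tests of list means between groups, 31 of 104 tests over 26 lists and 4 comparisons had p below 0.05 and 0 passed after Benjamini-Hochberg adjustment. The lowest adjusted value was 0.0563, and the smallest p that 6 against 6 arrays can give is 0.00216.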

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

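The tests of the thalamus pattern and of the array sets and the array set term were chosen after the results were seen. So were the tests of other probe sets in their forms with 1 probe set per gene. Splits and regroupings that use the array sets were also set after. The test of neighbouring genes and the counts over all other splits were set before. Single arrays far from the rest of their group were sought in 112 group values of lists and array measures, of which 19 stood apart, and in 884 group values of named genes, of which 68 did; chance alone picks about 1 in 20. Values below are the gap to the nearest array as a share of the group's range.

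Thalamus markers were lower in 6-week BPH/2J by -0.96, with replicate 2 inside the BPN/3J range. Sets A (replicates 1 to 4) and B (replicates 5 and 6) differed by 0.043 ± 0.131 within 26 weeks. Those sets exist only at 26 weeks, so this value cannot tell whether processing differed among the 6-week arrays, which was not tested. A strain difference of the same size at both ages does not account for the thalamus pattern, as the 26-week value was -0.0071 ± 0.118. All 16 members were lower, and the median correlation between pairs of members over the 6 mice was 0.908, consistent with less thalamic tissue in 5 of the dissected pieces. A difference in thalamic expression that is present in young BPH/2J and gone by 26 weeks stays open as untested. With the list mean as a covariate 155 genes were called at 6 weeks: 115 of the 306 shared by both ages (median size 0.51 before and 0.50 after) and 28 of the 1173 others (0.38 and 0.22), while the median SE went from 0.09 to 0.13.

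Age calls differed between the array sets. Over genes called from set A, the set B change rose by 0.189 ± 0.085 (jackknife SE) per unit of the set A change, 0.261 in BPH/2J and 0.117 in BPN/3J. A slope of 0 was set as the mark of the array sets as the whole cause, and 1 as that of age alone. The value was above 0 and 0.811 below 1. Choosing genes by their set A change pulls the slope below 1 even under age alone, so that distance cannot exclude age alone. Nor can a slope above 0 exclude processing as the cause, since both sets may differ from the 6-week arrays in it. What separates the sets, such as a processing date or an animal cohort, is not given in the labels and was not tested.

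Genes called between the strains at both ages lay next to each other in 18 pairs, against a mean of 4.67 and a highest of 14 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). This is in line with sequence differences carried in blocks of the genome, although a run of 5 protocadherin genes, Pcdhb5 to Pcdhb9, is a family whose probes may share targets, and pairs were also above their shuffles for genes called at 6 weeks alone (85 against 69.0) and with age in both strains (66 against 49.2). Other probe sets of these genes moved in the gene's direction in 23 of 26 cases, and the brightest other one in 17 of 19 genes (exact 95% interval 66.9% to 98.7%), which argues against variants under a single probe set as the whole cause in these 19; among the 11 whose other probe set was bright, the share was 81.8% (48.2% to 97.7%). Strain variants under the probes as the whole cause cannot be told apart from expression, since variants of a strain can lie under both probe sets of a gene and 287 genes had 1 probe set.

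Chance is excluded as the source of the whole count of genes called between strains at 6 weeks. There 1 of 100 splits, the real one, gave as many as 1479 (highest other 138). The same holds for the counts with age in BPH/2J (1 of 100, 3362 against 1154) and BPN/3J (1 of 100, 2445 against 8). The splits judge counts and not single genes, some of which can be false calls. At 26 weeks 5 of 100 splits gave as many as 532, with 3660 in the highest, so chance cannot be excluded in that form; 3 of the 4 others had all 4 set B arrays on one side, which points to a structure of the samples. With the array set as a term and 2 set B arrays on each side, 1 of 100 splits gave as many as the real 881 (highest other 144). For the interaction 1 of 100 regroupings gave as many as 6 (highest other 4). With residuals exchanged only among 6-week arrays and within each array set, added later, 1 of 100 did (highest other 1), and with the array set as a term 1 of 100 gave as many as 251 (highest other 6). These regroupings assume equal spread, and the median gene SD ran from 0.10 to 0.18 over the groups, so they cannot exclude chance for the interaction counts. The count was 0 in 14 of 24 fits without 1 array and 0 with the thalamus covariate, so the amount of thalamus in the 6-week pieces also stays open as the cause. Within a set, the strain count at 26 weeks was 536 in replicates 1 to 4 and 223 in replicates 5 and 6, the latter with 2 arrays per strain. Both fits shared their spread with the 6-week arrays, whose gene SDs were smaller, so these counts carry the same limit as the 532. Counts of called lists were as large in 35 of 100 splits for strain at 6 weeks (6 lists, highest other 15), 90 at 26 weeks (3, 12), 37 for the interaction (7, 12), 14 for age in BPH/2J (9, 12) and 98 in BPN/3J (2, 12), so chance cannot be excluded for any list count.

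In 6-week BPH/2J replicate 2, neuropeptide receptors (0.645) were low and the glutamate system (0.743), clock genes (0.7096) and voltage-gated channels (0.841) high; Gda (0.645), Coq8b (0.711), Baiap3 (0.732), Cartpt (0.738) and Th (0.642) were low, and Medag (0.694), Grin2a (0.675), Glul (0.722), Pde1b (0.665) and Cacnb4 (0.754) high. In replicate 5 Hcrt (0.640) and Sdhb (0.730) were low and Abca8a (0.689) and Mchr1 (0.644) high, and in replicate 6 red blood cell transcripts (0.688) were high and Ccl19 (0.762) low.

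In 6-week BPN/3J replicate 1, extracellular matrix genes (0.811), vascular markers (0.661) and Oasl2 (0.658) were high and Slc12a5 (0.716) and Foxp1 (0.765) low. In replicate 2 oxidative phosphorylation (0.760), Ndufa10 (0.717), Uqcrc1 (0.649), Hcn2 (0.693), Gjb1 (0.693), Opalin (0.678), Aspa (0.637) and Tyrobp (0.644) were low and Adra1b (0.650) high. Replicate 3 had high Nppc (0.656), replicate 4 low Ccl19 (0.846) and high Foxj1 (0.788), and replicate 6 high Htr1b (0.670). In replicate 5 neuropeptides (0.674) were low and thalamus markers (0.641), Kitl (0.666), Rora (0.757), Cacnb4 (0.752), Tnnt1 (0.662) and Plekhg1 (0.652) high.

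In 26-week BPH/2J replicate 3, the renin-angiotensin-aldosterone list (0.709), vascular (0.835), striatum (0.744) and cortex and hippocampus markers (0.640), Scn4b (0.699) and Pde10a (0.718) were high and Avp (0.729) low. In replicate 5 Phkg1 (0.738), Postn (0.666), Tbx19 (0.687) and Tac1 (0.646) were low and Grm2 (0.773) and Cry2 (0.666) high. In replicate 6 Sycp3 (0.714), Maob (0.665) and Gabra4 (0.802) were low and Th (0.698) high.

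In 26-week BPN/3J replicate 6, the median of the 6573 unnamed probe sets numbered below the first named one was 5.42 against at most 4.65 elsewhere (0.910); stress response genes (0.793), microglia markers (0.651), Eif4a3 (0.661), Hcrt (0.711), H2-Q4 (0.679) and Ifi27 (0.792) were low and Mir382 (0.807), Gabrd (0.749), Grm4 (0.717) and Grin2c (0.702) high. In replicate 5 Tcf7l2 (0.670), Kitl (0.739), Gabra4 (0.685), Prkg2 (0.749), Hlf (0.696), Kcnn3 (0.718), Tnnt1 (0.727), Plekhg1 (0.719), Lef1 (0.703) and Synpo2 (0.650) were low and Olig1 (0.672) high. Vascular markers were high in replicate 3 (0.703), and cortex and hippocampus markers (0.675) and Nr3c2 (0.654) in replicate 4.

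The strain difference itself differed between ages, by the interaction test, for Srpx2 (1.01), Slit2 (-0.99), N4bp2 (-0.88), Dgkk (-0.78), Ptpro (-0.78) and Coq8b (-0.56), which lost their calls in 14 to 21 of 24 fits without 1 array, and by camera for the means of thalamus markers (0.96), oligodendrocyte markers (0.37), voltage-gated channels (0.16), clock genes (0.16), oxidative phosphorylation (0.14), neuropeptide receptors (-0.17) and choroid plexus and ependymal markers (-0.48). With an estimated correlation none of these 7 lists was called (adjusted p = 0.565 to adjusted p = 0.773). Among 13120 probe sets outside the gene tests, 47 were higher and 42 lower in BPH/2J at both ages.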

How the results depend on the processing

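The array set term, each array set alone and the thalamus covariate were chosen after the data were seen; the cause of a move was not tested unless the setting itself removes arrays, genes or calls. For named genes 10754 of 11826 values kept direction and side of the threshold, 1049 kept direction but no longer passed, 6 newly passed and 17 turned. For lists these numbers were 905, 75, 0 and 1 of 981. Most values, 7584 for genes and 648 for lists, came from fits without 1 array, and single settings changed more. From replicates 5 and 6 alone 148 of 316 gene values stayed and 165 no longer passed. With the thalamus covariate 154 of 316 stayed and 157 no longer passed. With an estimated correlation 27 of 27 list values no longer passed.

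Interaction calls, 6 in all, were 34 after quantile normalisation, 67 without the dimmest genes, 31 with a variance trend, 683 with array weights, 0 at an adjusted p below 0.01, 251 with the array set term, 19 and 0 from replicates 1 to 4 and 5 and 6, and 0 with the thalamus covariate. The replicate block gave 27 interaction calls and changed no other count by over 1.5 times. Strain calls at 6 and 26 weeks were 2322 and 248 with only the groups compared, 765 and 291 at an adjusted p below 0.01, and 356 and 153 with a 1.5-fold minimum. At 6 weeks they were 3725 with array weights, 2460 with 26-week replicates 1 to 4 only and 155 with the covariate, and at 26 weeks 881 with the array set term and 223 from replicates 5 and 6. Age calls in BPH/2J and BPN/3J were 7475 and 6416 with array weights, 1407 and 435 at an adjusted p below 0.01, 338 and 108 with the fold minimum, 7843 and 6702 from replicates 1 to 4, 388 and 27 from replicates 5 and 6, and 8 in BPH/2J with the covariate. Called lists were 0 in every contrast with an estimated correlation, 0 at 26 weeks and 3 for the interaction with fry, and 3 for the interaction from replicates 5 and 6.

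Leaving out 1 array gave 1034 to 1961 strain calls at 6 weeks, 428 to 721 at 26 weeks, 0 to 496 for the interaction (0 without BPH/2J 6-week replicates 1, 3, 4 or 5 or 26-week 4 or 5, or BPN/3J 6-week 1, 3, 5 or 6 or 26-week 1, 2, 3 or 6), 2138 (without BPH/2J 26-week replicate 4) to 4838 for age in BPH/2J and 1034 (without BPN/3J 26-week replicate 4) to 4230 (without replicate 5) in BPN/3J. For age in BPN/3J it was 1299, 1521 and 1545 without 6-week replicates 1, 3 and 4, and 1382 and 1151 without 26-week replicates 1 and 2. Called lists numbered 6 to 7, 0 to 4, 7 to 9, 8 to 9 and 2 to 3 in that order, and the correlation of the strain differences 0.380 to 0.468.

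Atp5g1 at 6 weeks turned to 0.15 with the mean of its probe sets. With replicates 5 and 6 alone, choroid plexus markers with age in BPN/3J turned to -0.18, C1qb with age in BPH/2J to -0.062 and Per2 at 26 weeks to -0.027. With the covariate Gabrd (0.11), Prkg2 (0.0071), Cck (0.20), Crh (0.020) and Fos (0.43) turned at 6 weeks. Without 1 array, uncalled genes that changed sign ran from -0.200 to 0.022 (Fos) and -0.024 to 0.488 (Oxt) at 6 weeks, and from -0.027 to 0.157 (Agtr1a), -0.20004 to 0.030 (Npy) and -0.438 to 0.016 (Pomc) at 26 weeks. Arrays give no depth, and signal over background was not given.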

Other observations

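The genes here were named by the fixed rule, and the relation at the end was tested after the values were seen. Microglia markers held strain differences in both directions, with 1 higher and 4 lower of 17 at 6 weeks and 1 and 2 at 26 weeks (2 and 4, and 3 and 3, when adjusted over the list alone). C1qc and Laptm5 were lower in BPH/2J at both ages (Laptm5 by -0.44 ± 0.09 and -0.49 ± 0.09), while Tyrobp was higher at 26 weeks by 0.49 ± 0.12, though not past the test without BPH/2J replicate 2 or BPN/3J replicate 2 or 4 (highest adjusted p 0.0594). The redox enzyme gene Sod2 was lower at both ages, by -0.27 ± 0.05 and -0.18 ± 0.05 (the 26-week call was lost in 20 of 24 fits without 1 array, highest adjusted p 0.113), and Arg2, a mitochondrial arginase, was higher by 0.64 ± 0.11 and 0.62 ± 0.11. The serotonin receptor gene Htr5a was lower by -0.45 ± 0.07 and -0.47 ± 0.07.

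Lower with age in both strains by limma were Ccnd1, a cyclin, by -0.53 ± 0.08 in BPH/2J and -0.41 ± 0.08 in BPN/3J, and Sparc by -0.55 ± 0.09 and -0.37 ± 0.09. The growth and neurogenesis list had 6 lower and 1 higher of 23 genes in BPH/2J and 3 and 1 in BPN/3J (6 and 1, and 7 and 1, when adjusted over the list alone), and camera called it in neither strain. Fry called it in BPN/3J (adjusted p = 0.0377) and not in BPH/2J (adjusted p = 0.128). Sparc in BPN/3J was at -0.13 from replicates 5 and 6. The metallothionein gene Mt2 was lower by -0.71 ± 0.19 and -0.80 ± 0.19, though only by -0.18 and -0.09 from replicates 5 and 6, and Gclm, a glutathione synthesis subunit, by -0.34 ± 0.06 and -0.38 ± 0.06. From replicates 5 and 6 alone neither Ccnd1 (adjusted p = 0.0660 in BPH/2J and 0.144 in BPN/3J) nor Gclm (0.0683 and 0.0797) passed. That comparison rests on 2 arrays and has less power, so these losses do not by themselves show smaller changes. Across the 6 arrays of 6-week BPH/2J the thalamus and neuropeptide list means had r = -0.390 (exact permutation p = 0.443) and rho = 0.0286 (exact permutation p = 1), and r = 0.869 without the arrays farthest from the thalamus median, so the value depends on those arrays.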
